A study of Arabidopsis thaliana with 54 samples.

How the data were processed

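RNA of Arabidopsis thaliana seedlings, accession Col-0, was measured on 54 Affymetrix Gene 1.1 ST arrays. The arrays fall into 18 groups of 3, made of 2 tissues, 3 treatments and 3 harvest times. Per the labels' protocols, seedlings grew in short days and were moved at 1 day of age into airtight glass desiccators. There they stayed in control light, received ethylene at 1 µl per litre in the same light, or were shaded with a green filter. Photosynthetically active radiation was 140 in control light and 40 in shade, and blue light was 29 and 3, all in µmol per square metre and second, with a red to far-red ratio of 2.1 and 0.45. Hypocotyls, and cotyledons together with the shoot apical meristem, were separated with a needle at 1.5, 13.5 and 25.5 h, and the roots were discarded. The second harvest fell in the dark period and was dissected under a green safelight. Per the labels' protocols, replicates came from 3 independent experiments, and each replicate pooled the RNA of 2 technical replicates of 25 seedlings. The labels do not say which experiment each replicate number stands for.

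The deposited values are on the log2 scale and were made with RMA in Affymetrix Expression Console 1.4, per the submitters' processing notes. RMA corrects the background, equalizes the distributions and summarizes the probes of a feature. The notes also name Transcriptome Analysis Console 3.0, with no role stated. The log base was taken from the values, which lie between 0.360 and 13.97 with medians of 4.15 to 4.55 on all arrays, as RMA gives. The genome build, the array annotation and whether all arrays were normalized together are not given in the sources used here. No further centring was seen, and the values are levels, so no direction of a ratio had to be settled.

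The table holds 38408 features. The platform table pairs 16746 of them with exactly 1 gene, 758 with several and 20904 with none, so many well-known genes have no named feature here. Gene symbols were updated through gene identifiers to those of the TAIR10.1 assembly, which matched 16601 of the features with 1 gene. No coordinates are given, because the build of the array is unnamed. No gene was named from a feature with several. Features without a gene were left out of the main fit and its tests. They entered only a later fit over all features of the array. ETR2, ERS2, EBF2, PIL1, ATHB2 and HFR1, chosen beforehand as treatment checks, have no named feature and are not analysed here.

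All 54 arrays entered a single limma fit (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean for each of the 18 groups. The groups then share an estimate of the spread of each gene, with 4.67 prior degrees of freedom. Where the arrays of a group vary more than this estimate, its p-values can be too small. For AT1G52060 in hypocotyls at 1.5 h the SD was 3.63 in control and 0.18 in shade, while the standard error of the change was 1.15. Contrasts compared each treatment with its control within tissue and time, the response in hypocotyl with that in cotyledon, shade with ethylene, the control tissues, and control arrays at 25.5 h with those at 1.5 h. P-values were adjusted by the Benjamini-Hochberg method within each contrast over the 17504 features that carry a gene, and a feature was called at an adjusted p below 0.05. Counts of genes are counts of these features. Errors of changes are standard errors of this fit. The number of arrays limits the precision. On simulated data for the 12 treatment contrasts, over 17504 features, the fit recovered 13.4% to 28.4% of genes changed by 0.5, 74.6% to 88.1% of those changed by 1 and 95.5% to 100% of those changed by 2 on the log2 scale, with 3 to 10 false calls. The simulated noise was independent between genes and arrays, with the same spread of a gene in all groups, as the fit assumes. Groups with a wider spread or genes that vary together were not simulated, so the real arrays can give more false calls.

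Before the data were examined, 30 gene lists were fixed. Of these, 20 had under 3 measured genes and were not tested as lists, and the reference genes served only for centring. The other 9 (ethylene signalling, auxin response, gibberellin pathway, expansins and XTHs, chlorophyll biosynthesis, flavonoid and anthocyanin pathway, abscisic acid response, jasmonate and defence, stomatal lineage) were tested in the 12 treatment contrasts with camera in limma, which asks whether a list moves relative to the other genes. The preset correlation was 0.01, and p-values were adjusted over all 108 tests. Of these tests 25 were called, of which 11 held with a correlation estimated per list, and fry, which asks whether a list moves on balance 1 way, called 29. A gene with several features was represented by the brightest. Gene families were added after the data were seen.

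The genes named were set by a rule written before the data were examined. It takes the 3 largest rises and the 3 largest falls among the called features with exactly 1 gene, with all treated arrays on the same side of all control arrays in the treatment contrasts. For genes changed the same way by ethylene and shade it takes the 3 largest in each direction by the smaller of the changes, and from each described list up to 4 members by adjusted p. Overlaps between ethylene and shade share their control arrays. They were therefore set beside 20 simulations of unchanged groups, drawn around the means of those controls, and beside the overlap of independent lists. With 3 controls per group, the controls could not be split into parts of at least 2 arrays each.

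Alternatives fixed before the data were examined were the replicate number as a term, a trended and robust variance prior, fits on the arrays of a tissue or of the compared groups alone, quantile normalization again within each tissue, centring on 5 reference genes, leaving out the 30% dimmest features, an adjusted p below 0.01, leaving out each array in turn, a correlation estimated per list and the mean over the features of a gene. Chosen after the data were seen were adjusting over all features of the array, leaving out 7 arrays in which the mean of 3 jacalin-type lectin genes lay over 2 above its median on the log2 scale, that mean as a covariate, and the gene families. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.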

Results

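Seedlings of Arabidopsis thaliana were exposed for 1.5, 13.5 or 25.5 h to the gaseous hormone ethylene or to filtered, low red to far-red light that mimics a canopy, and their hypocotyls and cotyledons were measured on separate arrays. Each of the 18 groups held 3 arrays. Array medians lay between 4.15 and 4.55 on the log2 scale, and arrays of a group correlated at 0.966 to 0.983 across features. No pair of arrays held identical values. The first principal component carried 40.1% of the variance and the second 14.4%. Changes below are differences of group means on the log2 scale with standard errors, from 3 arrays per group, and the adjusted p-values are those of limma. In the treatment comparisons a gene rises or falls against the control of the same tissue and time. The controls also changed with time, so such a rise can reflect a falling control.

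**Figure D1:**
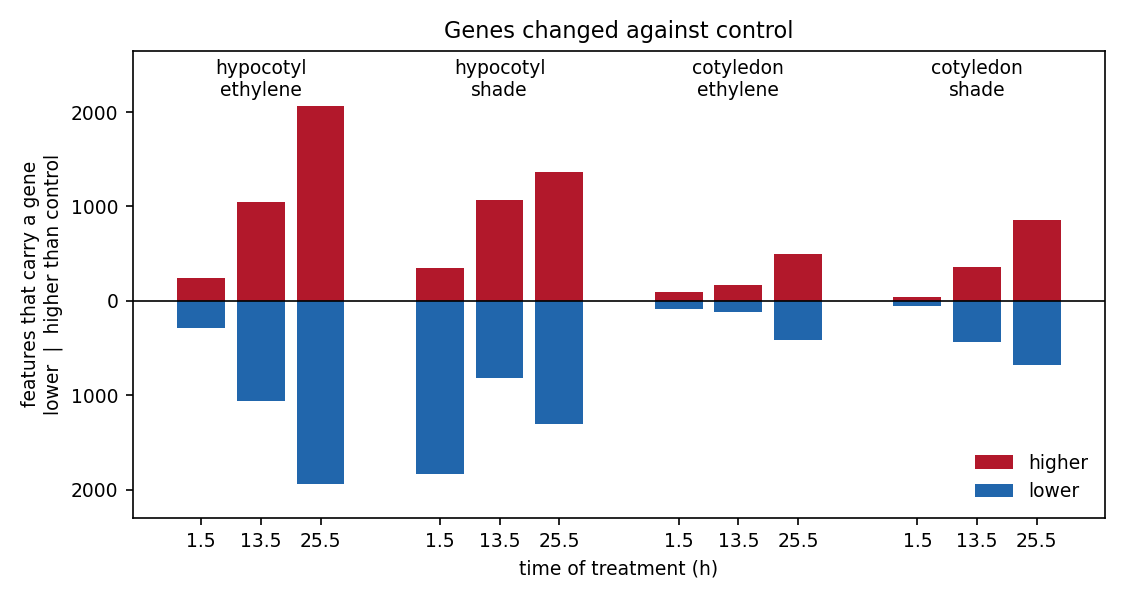
Bars give the number of features that carry a gene and were higher (above 0) or lower (below 0) than control, for each tissue, treatment and time in hours. Ethylene changed the most genes in hypocotyls at 25.5 h, with 2066 higher and 1941 lower, and shade the fewest in cotyledons at 1.5 h, with 36 higher and 56 lower.

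The first set of comparisons asks which genes ethylene changed in the hypocotyl, the organ that elongates in light-grown seedlings under both treatments. At 1.5 h the largest rises were those of AT1G44830, a transcription factor of the AP2/ERF family (3.38 ± 0.57, adjusted p = 1.1e-04), AT5G57760 (3.35 ± 0.65, adjusted p = 7.3e-04) and AT1G50110, a branched-chain aminotransferase (3.32 ± 0.30, adjusted p = 2.4e-10). The largest falls were those of AT1G60590, a pectin lyase-like protein (-3.58 ± 0.38, adjusted p = 1.1e-08), AT5G41900 (-3.14 ± 0.31) and AT1G58460 (-3.07 ± 0.22). Of the 4 measured ethylene signalling genes, 2 rose, also when adjusted over the list alone. These were ARL, a relative of the growth regulator ARGOS (2.66 ± 0.50), and RTE1, which acts on an ethylene receptor (1.92 ± 0.18), while EIN3 (0.09 ± 0.12) and RTH (-0.14 ± 0.18) did not pass. The list rose with an adjusted p of 8.9e-05 (adjusted p = 0.00952 with an estimated correlation). Of 7 expansins and XTHs, which loosen or remodel cell walls, 3 fell, also when adjusted over the list alone: XTH16 (-1.40 ± 0.31), EXPA15 (-0.97 ± 0.25) and XTH33 (-0.79 ± 0.21). That list fell with an adjusted p of 0.0045 (adjusted p = 0.0168 with an estimated correlation). The gibberellin receptors GID1A (-0.81 ± 0.17) and GID1C (0.69 ± 0.20) moved apart. In all, 242 genes were higher and 288 lower than control. Jacalin-type lectin genes averaged 7.28 and 7.78 in control replicates 1 and 3 and 3.79 in ethylene replicate 3, and the count was 199 without the 7 arrays high in these genes and 342 without ethylene replicate 2.

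At 13.5 h of ethylene, in the dark, hypocotyl AT3G49970, a member of the NPH3 family (5.16 ± 0.39, adjusted p = 8.2e-13), AT1G49570, a peroxidase (5.15 ± 0.21, adjusted p = 7.8e-22), and AT1G44830 (4.76 ± 0.57, adjusted p = 5.1e-08) rose the most. AT4G18220 (-3.85 ± 0.47, adjusted p = 7.6e-08), AT3G28270 (-3.43 ± 0.39) and the lectin-like AT3G16530 (-3.25 ± 0.44) fell the most. Among expansins and XTHs, 3 of 7 rose, namely XTH19 (4.05 ± 0.31), XTH33 (2.58 ± 0.21) and EXPA8 (2.02 ± 0.24), and EXPA15 fell (-0.97 ± 0.25), with the same counts adjusted over the list alone. The list rose with an adjusted p of 0.00199 (adjusted p = 0.0102 with an estimated correlation, and adjusted p = 0.0900 in a fit on the compared arrays alone). ARL (2.39 ± 0.50) and RTE1 (1.62 ± 0.18) were still raised, the only 2 of the 4 ethylene signalling genes to pass, also when adjusted over the list alone. That list had an adjusted p of 0.00759 (adjusted p = 0.0724 with an estimated correlation). HAT2, an auxin- and shade-responsive homeodomain factor, rose by 1.43 ± 0.17 and FHL, which carries phytochrome A to the nucleus, by 0.78 ± 0.24. The 100 genes with the largest excess in cotyledon over hypocotyl, taken over all arrays, averaged 4.54, 4.67 and 5.06 in these control hypocotyls and 4.01, 4.27 and 3.98 under ethylene. In this comparison 1051 genes were higher and 1058 lower. Lectin genes averaged 7.57 and 6.48 in control replicates 1 and 3 and 5.14 in ethylene replicate 1. Centring on reference genes moved the median of all genes to -0.12 and gave 634 higher and 1527 lower.

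At 25.5 h AT1G29025 (6.61 ± 0.60, adjusted p = 7.9e-12), AT1G44830 (6.51 ± 0.57, adjusted p = 4.1e-12) and AT5G57760 (5.67 ± 0.65, adjusted p = 2.8e-09) rose the most in the hypocotyl under ethylene. AT3G28270 (-6.91 ± 0.39, adjusted p = 2.1e-17), AT1G60590 (-5.82 ± 0.38, adjusted p = 1.2e-15) and AT2G27420, a cysteine proteinase (-5.12 ± 0.25, adjusted p = 5.7e-19), fell the most. Among expansins and XTHs, XTH19 (4.86 ± 0.31), XTH33 (3.08 ± 0.21), XTH18 (2.204 ± 0.43) and XTH16 (2.19 ± 0.31) rose and EXPA15 fell (-0.89 ± 0.25), 4 and 1 of 7 genes, also when adjusted over the list alone. The list rose with an adjusted p of 0.00161 (adjusted p = 0.00952 with an estimated correlation). XTH19 lay at 5.40, 5.57 and 5.21 in control hypocotyls at 1.5 h and at 1.22, 2.18 and 1.65 at 25.5 h. Under ethylene at 25.5 h it lay at 6.345, 6.82 and 6.47, so its change reflects in part the fall of the controls. AT5G57760 averaged 9.22 under ethylene at 1.5 h and 8.68 at 25.5 h, while its controls averaged 5.87 and 3.01. ARL rose by 4.1 ± 0.50 and RTE1 by 1.85 ± 0.18, 2 of 4 ethylene signalling genes on either adjustment, that is over all genes and adjusted over the list alone. Their list had an adjusted p of 0.0121 (adjusted p = 0.0929 with an estimated correlation, and adjusted p = 0.0556 without the dimmest features). SAUR10, a small auxin-induced gene, rose by 3.57 ± 0.24 and the gibberellin receptor GID1B by 1.28 ± 0.27, while PIF7, a bHLH factor of shade signalling, fell by 1.42 ± 0.25. PORB, an enzyme of chlorophyll synthesis, rose by 1.21 ± 0.28 and CHLM of the same pathway fell by 0.89 ± 0.11. The 100 cotyledon genes averaged 4.75, 4.59 and 4.97 in controls and 3.77, 3.61 and 4.01 here. There were 2066 higher and 1941 lower genes, of which 688 and 712 changed by at least 2-fold. Centring on reference genes moved the median of all genes to -0.17 and gave 1339 higher and 2803 lower.

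The same comparison was made for shade. At 1.5 h in the hypocotyl, AT1G22690, a gibberellin-regulated GASA peptide (2.33 ± 0.46, adjusted p = 6.2e-04), RTFL13 (1.89 ± 0.33, adjusted p = 1.1e-04) and AT1G49032 (1.78 ± 0.30, adjusted p = 7.2e-05) rose the most. The largest falls were those of the jacalin-type lectins AT1G52060 (-4.58 ± 1.15, adjusted p = 0.00607) and AT1G52050 (-4.08 ± 0.98, adjusted p = 0.00435) and of AT3G27950, a GDSL lipase (-3.83 ± 0.73, adjusted p = 3.9e-04). These 3 falls rest on control replicates 1 and 3, in which the lectins averaged 7.28 and 7.78. Without the 7 arrays high in lectins they came to -0.42 (adjusted p = 0.707), -0.39 (adjusted p = 0.676) and -0.95 (adjusted p = 0.0583), which for the lectins follows from how those arrays were picked. Over all alternatives their adjusted p reached 0.948, 0.676 and 0.0865, and leaving out control replicate 1 or 3 alone ended the calls of AT1G52060 (0.0560 and 0.0872) and AT1G52050 (0.0539 and 0.0611). IAA29, an auxin-induced repressor, was the only 1 of 4 auxin response genes to rise (0.80 ± 0.26), against 2 adjusted over the list alone. The list rose with an adjusted p of 0.0096 (adjusted p = 0.0929 with an estimated correlation). FHL (0.87 ± 0.24), XTH16 (0.95 ± 0.31), EXPA8 (0.72 ± 0.24) and XTH33 (0.65 ± 0.21) rose, while GID1B (-1.26 ± 0.27), GID1A (-0.60 ± 0.17) and HYH, a bZIP factor of light signalling (-0.65 ± 0.15), fell. Shade left 343 genes higher and 1836 lower, with a median over all genes of -0.116. After quantile normalization within the tissue 795 were higher and 696 lower, and after centring on reference genes 373 and 980. The count of 2179 genes came to 372 without the 7 arrays high in lectins, which leaves 1 control array assumed to vary like the other groups, to 1090 with the lectins as a covariate and to 1335 without control replicate 3.

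At 13.5 h of shade, in the dark, AT5G35525 (3.84 ± 0.32, adjusted p = 2.4e-11), the GDSL lipase AT4G28780 (3.81 ± 0.29, adjusted p = 2.5e-12) and AT4G17470 (3.61 ± 0.27, adjusted p = 2.5e-12) rose the most in the hypocotyl. BGLU21, a beta-glucosidase (-3.94 ± 1.05, adjusted p = 0.0092), AT1G52050 (-3.90 ± 0.98, adjusted p = 0.00543) and AT3G28270 (-3.50 ± 0.39, adjusted p = 1.5e-08) fell the most. The control arrays differed in lectins here too, at 7.57 and 6.48 in replicates 1 and 3. Without the 7 arrays BGLU21 and AT1G52050 changed by -1.05 (adjusted p = 0.566) and -0.12 (adjusted p = 0.934). Leaving out control replicate 1 alone ended both calls (adjusted p = 0.123 and 0.0970), and control replicate 3 that of AT1G52050 (adjusted p = 0.0562). Of 5 flavonoid and anthocyanin genes, 3 fell, or 4 adjusted over the list alone: DFR, an enzyme at the branch to anthocyanins (-3.39 ± 0.68), and the glycosyltransferases UGT79B1 (-1.78 ± 0.56) and UGT75C1 (-1.36 ± 0.45). The list fell with an adjusted p of 0.00181 (adjusted p = 0.229 with an estimated correlation). DFR lay at 7.95 and 8.81 in control replicates 1 and 3, the arrays high in lectins, and at 4.03 in replicate 2, against 3.53, 3.29 and 3.802 in shade, so its fall rests on those 2 arrays. EXPA8 (2.19 ± 0.24), IAA29 (1.48 ± 0.26), FHL (1.27 ± 0.24), XTH16 (0.95 ± 0.31) and EPFL9, a peptide that promotes stomata (0.74 ± 0.22), rose. EXPA4 (-1.41 ± 0.30), HYH (-1.27 ± 0.15) and GID1B (-1.19 ± 0.27) fell, as did the zinc finger gene STZ, here also under its other name ZAT10 (-2.67 ± 0.71). The 100 cotyledon genes averaged 4.07, 4.05 and 4.42 here, below all controls (4.54, 4.67 and 5.06). In total 1068 genes were higher and 822 lower, and 1190 were called without shade replicate 1.

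At 25.5 h AT3G06990 (4.71 ± 0.34, adjusted p = 3.9e-14), the Dof transcription factor AT1G69570 (4.52 ± 0.21, adjusted p = 9.0e-20) and AT1G72140, of the nitrate and peptide transporter family (4.21 ± 0.27, adjusted p = 3.7e-15), rose the most in the hypocotyl under shade. DFR (-4.53 ± 0.68, adjusted p = 2.0e-06), AT4G29030 (-3.87 ± 0.84, adjusted p = 6.3e-04) and the sugar transporter gene SAG29 (-3.82 ± 0.38, adjusted p = 2.6e-10) fell the most. All 5 flavonoid and anthocyanin genes fell, also when adjusted over the list alone, with UGT79B1 at -2.71 ± 0.56, UGT75C1 at -2.53 ± 0.45 and the acyltransferase 5MAT at -2.24 ± 0.43. The list had an adjusted p of 1.1e-05 (adjusted p = 0.0596 with an estimated correlation). Of 7 expansins and XTHs, XTH16 (3.19 ± 0.31), XTH33 (2.04 ± 0.21), XTH19 (1.94 ± 0.31) and EXPA8 (1.62 ± 0.24) rose, and EXPA4 (-1.77 ± 0.30) and EXPA15 (-1.49 ± 0.25) fell, so 4 rose and 2 fell, against 5 and 2 adjusted over the list alone. That list rose with an adjusted p of 0.0096 (adjusted p = 0.0314 with an estimated correlation, 0.0509 without the dimmest features and 0.0545 without shade replicate 1). XTH19 lay at 3.65, 3.88 and 3.34 under shade, above its controls at 25.5 h but below the 5.40, 5.57 and 5.21 of controls at 1.5 h. The gibberellin receptors GID1B (-1.44 ± 0.27) and GID1A (-0.67 ± 0.17) fell and GID1C did not pass (-0.46 ± 0.20), 2 of 3 genes, against 3 adjusted over the list alone. The list fell with an adjusted p of 0.0120 (adjusted p = 0.0834 with an estimated correlation and 0.0509 without the dimmest features). The dark-induced genes AT3G15450 (SEN5, 2.71 ± 0.40) and AKINBETA1 (1.25 ± 0.20) rose, as did FHL (2.09 ± 0.24), SAUR10 (1.97 ± 0.24), EPFL9 (1.47 ± 0.22) and PORB (1.27 ± 0.28). Shade left 1369 genes higher and 1309 lower at this time. Centring on reference genes moved the median of all genes to -0.10 and gave 938 higher and 1888 lower.

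**Figure D2:**
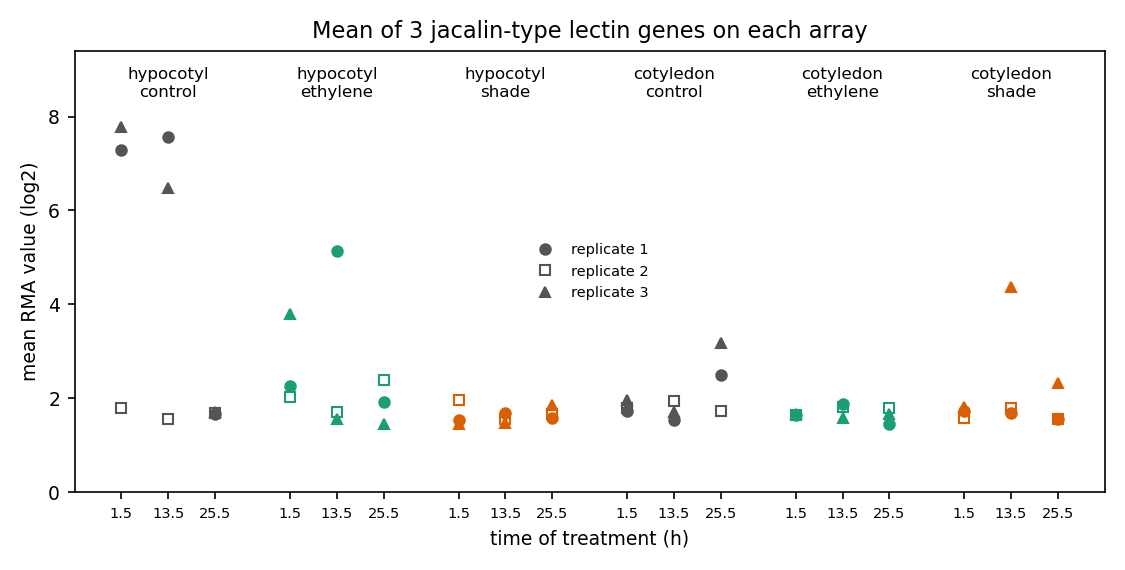
Each point is the mean RMA value (log2) of 3 jacalin-type lectin genes on an array, by tissue, treatment and time in hours, with a symbol for each replicate number. Control hypocotyls at 1.5 h stood at 7.28 and 7.78 in replicates 1 and 3, and at 13.5 h at 7.57 and 6.48.

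**Figure D3:**
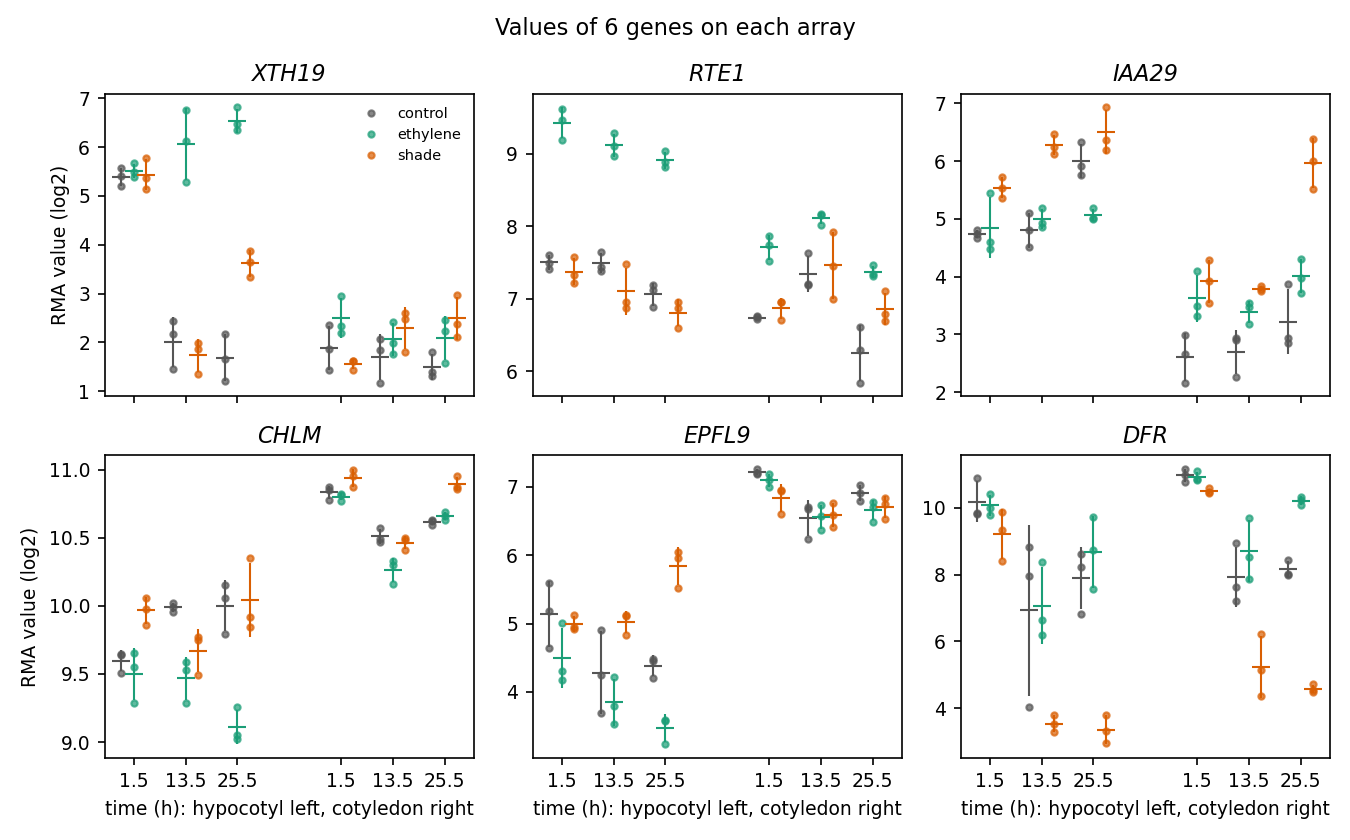
Points are the RMA values (log2) of XTH19, RTE1, IAA29, CHLM, EPFL9 and DFR on each array against time in hours, hypocotyl left and cotyledon right, with the mean as a dash and the SD of 3 arrays as a bar. The gene with the smallest adjusted p of each of 6 lists is drawn, and DFR under shade at 25.5 h was 4.53 lower than control in hypocotyls and 3.56 lower in cotyledons on the log2 scale.

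Ethylene was compared with control in the cotyledon samples in the same way. At 1.5 h AT3G20395 (3.74 ± 0.64, adjusted p = 3.2e-04), AT5G57760 (2.85 ± 0.65, adjusted p = 0.0121) and ARL (2.84 ± 0.50, adjusted p = 5.4e-04) rose the most. The GDSL lipase AT1G29660 (-2.92 ± 0.50, adjusted p = 3.2e-04), AT1G76620 (-1.97 ± 0.26, adjusted p = 5.7e-06) and AT1G58460 (-1.94 ± 0.22, adjusted p = 2.3e-07) fell the most. ARL and RTE1 (0.97 ± 0.18) were the 2 of 4 ethylene signalling genes that rose, also when adjusted over the list alone, and the list had an adjusted p of 8.0e-05 (adjusted p = 0.00952 with an estimated correlation). IAA29 rose by 1.02 ± 0.26 and XTH33 fell by 0.79 ± 0.21. In this comparison 93 genes were higher and 83 lower, or 106 and 57 after centring on reference genes. The count of 176 genes came to 111 without control replicate 1, 111 without ethylene replicate 1 and 113 without ethylene replicate 2, and each of these also ended the call of AT5G57760 (adjusted p = 0.0684, 0.0596 and 0.0506). IAA29 lost its call without control replicate 1 (0.106) or 3 (0.302) or ethylene replicate 1 (0.305) or 3 (0.0646), and after quantile normalization (0.0516).

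At 13.5 h AT5G57760 (3.12 ± 0.65, adjusted p = 0.00333), AT4G11610 (3.06 ± 0.35, adjusted p = 1.9e-07) and the ERF factor AT1G36060 (2.94 ± 0.61, adjusted p = 0.00372) rose the most in cotyledons under ethylene. AT3G46490 (-2.41 ± 0.34, adjusted p = 1.4e-05), AT4G19380 (-2.33 ± 0.25, adjusted p = 6.6e-08) and the lectin-like AT3G15356 (-2.19 ± 0.26, adjusted p = 3.1e-07) fell the most. ARL (2.31 ± 0.50) and RTE1 (0.77 ± 0.18) rose, 2 of 4 ethylene signalling genes, against 3 adjusted over the list alone, and the list had an adjusted p of 8.0e-05 (adjusted p = 0.00952 with an estimated correlation). GH3.5, an enzyme that conjugates auxin, rose by 1.09 ± 0.23, the only 1 of 4 auxin response genes, against 2 adjusted over the list alone. That list had an adjusted p of 0.0230 (adjusted p = 0.144 with an estimated correlation, 0.259 without control replicate 1, 0.0869 without ethylene replicate 2 and 0.0509 without the dimmest features). None of 5 flavonoid and anthocyanin genes was called, also when adjusted over the list alone. Their list rose with an adjusted p of 0.0498, which became 0.523 (adjusted p with an estimated correlation) and 0.0520 after quantile normalization, 0.0910 without the dimmest features, 0.0626 with the compared arrays alone, and 0.307, 0.234 and 0.525 without control replicate 1, control replicate 2 or ethylene replicate 3. Here 166 genes were higher and 116 lower, and the 282 came to 179 and 141 without control replicates 1 and 2 and to 185 without ethylene replicate 2. The same control arrays decided the calls of AT5G57760 (adjusted p = 0.0543 without replicate 1 and 0.0544 without replicate 2) and AT1G36060 (0.0658 without replicate 2).

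At 25.5 h AT3G20395 (4.61 ± 0.64, adjusted p = 2.3e-06), ARL (4.53 ± 0.50, adjusted p = 2.3e-08) and AT5G57760 (4.14 ± 0.65, adjusted p = 2.0e-05) rose the most in cotyledons under ethylene. The thionin AT1G66100 (-4.40 ± 0.49, adjusted p = 2.5e-08), AT1G65490 (-3.63 ± 0.26, adjusted p = 4.5e-13) and AT3G46490 (-3.29 ± 0.34, adjusted p = 3.1e-09) fell the most. Of 5 flavonoid and anthocyanin genes, 5MAT (2.31 ± 0.43), UGT79B1 (1.90 ± 0.56) and UGT75C1 (1.78 ± 0.45) rose, so 3 over all genes and 4 adjusted over the list alone. DFR did not pass over all genes (2.06 ± 0.68). The list rose with an adjusted p of 1.1e-04 (adjusted p = 0.116 with an estimated correlation). ARL and RTE1 (1.12 ± 0.18) were 2 of 4 ethylene signalling genes that rose, also when adjusted over the list alone, with an adjusted p of 8.9e-05 for the list (adjusted p = 0.00952 with an estimated correlation). GH3.5 rose by 0.95 ± 0.23, 1 of 4 auxin response genes against 2 adjusted over the list alone, with an adjusted p of 0.0128 for the list (adjusted p = 0.109 with an estimated correlation, 0.0563 without control replicate 2 and 0.0509 without the dimmest features). PORB (1.21 ± 0.28) and GID1B (0.99 ± 0.27) rose, and XTH16 fell by 1.07 ± 0.31. There were 497 higher and 413 lower genes. The 910 came to 605 without ethylene replicate 3, and centring on reference genes moved the median of all genes to -0.13 and gave 260 higher and 750 lower.

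Shade changed few genes in cotyledons at 1.5 h. AT1G02610 (1.88 ± 0.35, adjusted p = 0.00203), AT3G15450 (SEN5, 1.82 ± 0.40, adjusted p = 0.0134) and AT4G27450 (1.76 ± 0.31, adjusted p = 0.00139) rose the most. The GASA peptide AT3G10185 (-2.21 ± 0.31, adjusted p = 4.9e-05), AT4G34550 (-2.13 ± 0.30, adjusted p = 4.9e-05) and AT2G36970 (-1.93 ± 0.32, adjusted p = 6.3e-04) fell the most. AKINBETA1, a subunit of the starvation kinase SnRK1, rose by 1.02 ± 0.20. IAA29 rose by 1.31 ± 0.26, the only 1 of 4 auxin response genes on either adjustment, that is over all genes and adjusted over the list alone. The list rose with an adjusted p of 0.00171 (adjusted p = 0.0396 with an estimated correlation). None of 5 flavonoid and anthocyanin genes was called, also when adjusted over the list alone, with DFR at -0.48 ± 0.68. Their list fell with an adjusted p of 0.0120 (adjusted p = 0.401 with an estimated correlation, 0.0558 without control replicate 1 and 0.0557 without shade replicate 3). Counts were 36 higher and 56 lower, or 44 and 40 after quantile normalization. The 92 genes came to 53 and 58 without shade replicates 2 and 3, and AT3G15450 lost its call without control replicate 1 or 2 or shade replicate 2 or 3 (adjusted p 0.0655 to 0.180). IAA29 lost its call without shade replicate 1 (0.0679) or control replicate 3 (0.0748).

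At 13.5 h of shade, in the dark, AT5G44440, a berberine bridge enzyme-like protein (4.00 ± 0.52, adjusted p = 3.9e-06), AT1G12080 (2.19 ± 0.26, adjusted p = 5.2e-07) and the expansin EXPB1 (1.69 ± 0.30, adjusted p = 4.3e-04) rose the most in cotyledons. DFR (-2.68 ± 0.68, adjusted p = 0.0132), the MATE transporter AT2G04050 (-2.49 ± 0.35, adjusted p = 1.2e-05) and AT4G03292 (-2.33 ± 0.42, adjusted p = 4.3e-04) fell the most. Of 5 flavonoid and anthocyanin genes 3 fell, also when adjusted over the list alone: DFR, UGT79B1 (-1.96 ± 0.56) and 5MAT (-1.53 ± 0.43). The list fell with an adjusted p of 0.00106 (adjusted p = 0.187 with an estimated correlation). EXPA8 was the only 1 of 7 expansins and XTHs to rise (1.25 ± 0.24), against 2 adjusted over the list alone, and their list rose with an adjusted p of 0.0045 (adjusted p = 0.0168 with an estimated correlation). IAA29 rose by 1.09 ± 0.26. AT3G15450 (-0.43 ± 0.40) and AKINBETA1 (0.02 ± 0.20) did not pass at this time. There were 358 higher and 437 lower genes, or 389 and 271 after centring on reference genes. Lectin genes averaged 4.37 in shade replicate 3. The 795 genes came to 489 and 443 without control replicates 1 and 2 and to 479 without shade replicate 1, and DFR lost its call without shade replicate 1 (adjusted p = 0.0987) or control replicate 3 (adjusted p = 0.102).

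At 25.5 h AT5G44440 (3.01 ± 0.52, adjusted p = 9.1e-05), the bHLH factor AT3G21330 (2.82 ± 0.26, adjusted p = 4.5e-10) and AT4G36850 (2.79 ± 0.29, adjusted p = 4.6e-09) rose the most in shaded cotyledons. The beta-glucosidase BGLU28 (-3.57 ± 0.41, adjusted p = 4.1e-08), DFR (-3.56 ± 0.68, adjusted p = 3.2e-04) and STZ (-3.47 ± 0.71, adjusted p = 8.9e-04) fell the most. Of 5 flavonoid and anthocyanin genes 4 fell, or 5 adjusted over the list alone, among them UGT75C1 (-2.17 ± 0.45) and UGT79B1 (-1.90 ± 0.56). The list fell with an adjusted p of 8.0e-05 (adjusted p = 0.0959 with an estimated correlation). IAA29 (2.75 ± 0.26) and GH3.5 (1.04 ± 0.23) rose, 2 of 4 auxin response genes on either adjustment, that is over all genes and adjusted over the list alone, with an adjusted p of 0.00132 for the list (adjusted p = 0.0340 with an estimated correlation). ARL (1.77 ± 0.50), RTE1 (0.61 ± 0.18) and EIN3 (0.55 ± 0.12) rose as well, 3 of 4 ethylene signalling genes, also when adjusted over the list alone, with an adjusted p of 0.0045 for the list (adjusted p = 0.0582 with an estimated correlation). AT3G15450 (1.99 ± 0.40), AKINBETA1 (1.81 ± 0.20), FHL (1.38 ± 0.24), PORB (1.64 ± 0.28) and HAT2 (0.98 ± 0.17) were higher. In all 859 genes were higher and 683 lower, against 1236 and 579 after quantile normalization. Centring on reference genes moved the median of all genes to -0.14 and gave 377 higher and 1311 lower, and 1001 genes were called without control replicate 1.

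No contrast was called for the chlorophyll biosynthesis list (lowest adjusted p = 0.146 over the 12 contrasts), the stomatal lineage list (0.115), the abscisic acid response list (0.559) or the jasmonate and defence list (0.633). Single members of the first 3 passed, among them PORB, GSA1 (-0.60 ± 0.13 in hypocotyls after 1.5 h of shade), EPFL9, SPCH (-1.14 ± 0.40 in hypocotyls after 25.5 h of shade) and KIN2 (-1.03 ± 0.31 in hypocotyls after 25.5 h of ethylene). The root hair expansins EXPA7 and EXPA18, measured because hypocotyl samples could hold root cells, passed in none of the 12 treatment contrasts, with changes of -0.73 ± 0.40 and -0.12 ± 0.55 in hypocotyls after 1.5 h of shade. EXPA7 itself lay at 7.23, 6.91 and 5.39 in the 3 control hypocotyls at 1.5 h and at 3.07, 2.80 and 3.196 at 25.5 h, against 3.39, 3.07 and 3.08 in control cotyledons at 1.5 h, so the missing calls do not show that root cells were absent. The meristem genes CLV3 and UFO, measured because the cotyledon samples hold the meristem, passed in none either, with changes of -0.11 ± 0.17 and 0.06 ± 0.22 in cotyledons after 25.5 h of shade.

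A further set of comparisons asks whether the response differs between the tissues, as the change in hypocotyl minus the change in cotyledon. The sign of this difference does not by itself say which tissue responded more strongly. For ethylene at 1.5 h, RTFL14 (2.84 ± 0.57, adjusted p = 0.0142), AT2G43870 (2.62 ± 0.48, adjusted p = 0.00453) and AT5G67020 (2.56 ± 0.47, adjusted p = 0.00453) were more positive in hypocotyl. AT1G61840 (-2.33 ± 0.44), AT5G41900 (-2.03 ± 0.44) and AT1G69570 (-1.73 ± 0.29) were more negative. At 13.5 h the peroxidases AT1G49570 (4.56 ± 0.30, adjusted p = 2.3e-14) and AT5G19890 (4.19 ± 0.42) and XTH19 (3.68 ± 0.44) stood highest, and AT5G44440 (-3.27 ± 0.74, adjusted p = 0.00623), AT3G62550 (-2.84 ± 0.39) and AT4G18220 (-2.76 ± 0.67) lowest. At 25.5 h AT1G29025 (5.92 ± 0.84, adjusted p = 1.2e-06), the expansin-like EXLA2 (5.85 ± 0.50) and AT1G53690 (4.82 ± 0.43) stood highest, and AT3G28270 (-6.43 ± 0.55, adjusted p = 2.7e-11), AT1G60590 (-4.65 ± 0.54) and SIS (-4.57 ± 0.28) lowest. The difference was called for 24, 547 and 2582 genes at the 3 times, with 18, 306 and 1238 more positive in hypocotyl and 6, 241 and 1344 more negative. After centring on reference genes the split was 12 and 8 at 1.5 h and, with the median of all genes at -0.12, 178 and 343 at 13.5 h. The count came to 13 without the arrays high in lectins and to 88 without hypocotyl control replicate 2 at 1.5 h and to 305 without hypocotyl ethylene replicate 3 at 13.5 h. RTFL14 and AT5G41900 lost their calls without several single arrays, among them hypocotyl ethylene replicate 1 (0.0963) for RTFL14 and replicate 3 (0.159) for AT5G41900, and AT4G18220 without hypocotyl ethylene replicate 2 (0.0637). Both tissues changed together in many genes, with 59 higher and 41 lower at 1.5 h where independent lists would share 1.29 and 1.37.

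For shade at 1.5 h the GASA peptides AT1G22690 (2.58 ± 0.65, adjusted p = 0.0264) and AT3G10185 (2.38 ± 0.44, adjusted p = 0.00191) and AT3G52170 (2.09 ± 0.31) were more positive in hypocotyl. AT3G27950 (-3.70 ± 1.03, adjusted p = 0.0450), AT1G50060 (-3.20 ± 0.89, adjusted p = 0.0451) and AT2G41810 (-3.05 ± 0.85, adjusted p = 0.0445) were more negative. At 13.5 h AT5G35525 (3.89 ± 0.45, adjusted p = 9.6e-07), AT5G41900 (3.36 ± 0.44) and AT4G17470 (3.11 ± 0.39) stood highest, and AT1G52050 (-4.98 ± 1.39, adjusted p = 0.0313), the cysteine proteinase CP1 (-3.91 ± 0.69) and AT5G01870 (-3.88 ± 0.90) lowest. At 25.5 h AT4G11210 (4.45 ± 0.70, adjusted p = 3.0e-05), AT1G72140 (4.38 ± 0.39) and AT3G06990 (4.28 ± 0.48) stood highest, and AT4G29030 (-3.83 ± 1.18, adjusted p = 0.0447), AT5G44572 (-3.32 ± 0.54) and AT3G16530 (-3.28 ± 0.62) lowest. The difference was called for 378, 685 and 986 genes, with 72, 372 and 480 more positive in hypocotyl and 306, 313 and 506 more negative. At 1.5 h the split was 91 and 80 after quantile normalization and 48 and 95 after centring, and at 13.5 h centring, with the median of all genes at -0.11, gave 185 and 388. The 378 came to 88 without the arrays high in lectins. Left out singly, hypocotyl control replicates 1 and 3 gave 226 and 247, hypocotyl shade replicates 1 and 3 gave 251 and 201, cotyledon controls 235, 200 and 243, and cotyledon shade arrays 247, 206 and 200. The 685 came to 329 without hypocotyl shade replicate 1 and 433 without cotyledon control replicate 2. Of the genes named, AT3G27950, AT1G50060 and AT2G41810 lost their calls without any of the single arrays but hypocotyl control replicate 2 and changed by -0.81, -0.42 and -0.83 without the arrays high in lectins, AT1G52050 by -0.28. AT1G52050 also lost its call without hypocotyl control replicate 1 (0.127) or cotyledon shade replicate 3 (0.117), among others. AT4G29030 also lost its call without most single arrays (0.121 without hypocotyl control replicate 3), AT5G01870 without hypocotyl shade replicate 1 (0.0521) and AT1G22690 without any of several arrays, among them cotyledon shade replicate 2 (0.0723).

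Another question is which genes ethylene and shade change the same way. In hypocotyls at 1.5 h RTFL14 (2.77 ± 0.40 with ethylene, 1.38 ± 0.40 with shade), AT2G36220 (1.198 ± 0.31, 0.97 ± 0.31) and AT3G14560 (1.17 ± 0.19, 0.92 ± 0.19) rose under both, and AT5G54370 (-3.08 ± 0.89, -3.63 ± 0.89), sks15 (-2.66 ± 0.70, -3.13 ± 0.70) and AT1G50060 (-2.57 ± 0.63, -3.16 ± 0.63) fell under both. These 3 falls rest on control replicates 1 and 3, high in lectins. Without the 7 arrays they were -0.33, -0.03 and 0.25 with ethylene and -0.43, -0.29 and -0.39 with shade (adjusted p 0.686 to 1). With ethylene, control replicates 1 and 3 each ended the calls of AT5G54370 (0.403 and 0.330), sks15 (0.244 and 0.282) and AT1G50060 (0.248 and 0.150), and ethylene replicate 1 those of AT5G54370 (0.183) and sks15 (0.173), ethylene replicate 2 that of AT5G54370 (0.179). With shade, control replicates 1 and 3 ended the call of AT5G54370 (0.0646 and 0.0604), and control replicates 2 and 3 and shade replicate 2 that of RTFL14 (0.0571, 0.160 and 0.0887). AT2G36220 lost its calls without control replicate 1 (0.130 with ethylene, 0.134 with shade) or 2 (0.101 and 0.139), ethylene replicate 2 (0.0981) or 3 (0.147), or any shade array (0.0544 to 0.128). At 13.5 h the GDSL lipase AT2G42990 (2.39 ± 0.32, 2.60 ± 0.32), AT1G53690 (2.31 ± 0.30, 2.94 ± 0.30) and EXPA8 (2.02 ± 0.24, 2.19 ± 0.24) rose, and AT3G28270 (-3.43 ± 0.39, -3.50 ± 0.39), AT3G06460 (-2.52 ± 0.83, -2.95 ± 0.83) and CP1 (-2.20 ± 0.49, -3.07 ± 0.49) fell. Without the 7 arrays AT3G06460 changed by -0.33 (adjusted p = 0.746) and -0.12 (adjusted p = 0.933), and CP1 by -1.80 with ethylene (adjusted p = 0.101). AT3G06460 also lost its calls without control replicate 1 (0.376 with ethylene, 0.197 with shade) or 3 (0.153 and 0.0722) or ethylene replicate 2 (0.159) or 3 (0.151). At 25.5 h AT5G35525 (3.84 ± 0.32, 3.88 ± 0.32), AT3G05150 (4.74 ± 0.40, 3.66 ± 0.40) and EXLA2 (3.53 ± 0.35, 4.09 ± 0.35) rose, and AT3G16530 (-4.26 ± 0.44, -3.71 ± 0.44), AT3G28270 (-6.91 ± 0.39, -3.58 ± 0.39) and AT3G46880 (-3.49 ± 0.28, -3.35 ± 0.28) fell. The same way went 88, 572 and 1456 genes, and opposite ways 61, 123 and 173. Higher with ethylene but lower with shade were 33, 43 and 76, where independent lists would share 25.4, 49.4 and 154.5. Lower with ethylene but higher with shade were 28, 80 and 97, where they would share 5.64, 64.55 and 151.8. Higher under both were 10, 274 and 762 where independent lists would share 4.74, 64.1 and 162, and lower under both were 78, 298 and 694 where they would share 30.2, 49.7 and 145. In 20 simulations of unchanged groups, drawn around the control means, no gene went the same way. With no true change hardly any gene can be called, so this count cannot measure what the shared controls add. Part of the excess may still come from the shared controls, which could not be split into parts of at least 2 arrays each, and the 88 came to 9 without the arrays high in lectins. Across genes the changes correlated at 0.260, 0.293 and 0.458, against 0.5002, 0.501 and 0.4999 simulated, and their covariance was 0.0338, 0.0567 and 0.141, against 0.0239, 0.0238 and 0.0238. The 88 came to 24, 273 and 44 without control replicates 1, 2 and 3 and to 38 without ethylene replicate 1 or without ethylene replicate 2.

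In cotyledons at 1.5 h IAA29 (1.02 ± 0.26, 1.31 ± 0.26) was the only gene higher under both, and AT3G10185 (-1.53 ± 0.31, -2.21 ± 0.31), AT1G23205 (-1.81 ± 0.24, -1.37 ± 0.24) and TBL26, of a family that acetylates wall polymers (-1.25 ± 0.22, -1.50 ± 0.22), were lower. At 13.5 h AT3G60070 (1.09 ± 0.26, 1.204 ± 0.26), TBL37 (0.94 ± 0.17, 1.21 ± 0.17) and AT4G13540 (0.92 ± 0.23, 0.81 ± 0.23) rose, and AT2G27610 (-1.52 ± 0.23, -1.39 ± 0.23), AT5G56840 (-1.24 ± 0.25, -1.36 ± 0.25) and AT5G14580 (-1.14 ± 0.25, -1.55 ± 0.25) fell. At 25.5 h AT5G44440 (2.73 ± 0.52, 3.01 ± 0.52), AT5G62280 (2.19 ± 0.40, 2.33 ± 0.40) and AT3G55240 (2.99 ± 0.33, 2.12 ± 0.33) rose, and TBL26 (-2.93 ± 0.22, -3.13 ± 0.22), STZ (-2.73 ± 0.71, -3.47 ± 0.71) and AT2G29500 (-2.41 ± 0.36, -3.11 ± 0.36) fell. The same way went 10, 46 and 206 genes, and opposite ways 1, 16 and 59. Higher with ethylene but lower with shade were 0, 3 and 17, where independent lists would share 0.298, 4.14 and 19.4. Lower with ethylene but higher with shade were 1, 13 and 42, where they would share 0.171, 2.37 and 20.3. Higher under both were 1, 22 and 128 where independent lists would share 0.191, 3.39 and 24.4, and lower under both were 9, 24 and 78 where they would share 0.266, 2.90 and 16.1. No gene went the same way in the simulations, which cannot measure what the shared controls add. Part of the excess of genes changed the same way may come from the shared controls. Correlations were 0.383, 0.357 and 0.315 against 0.499, 0.5003 and 0.502 simulated, with covariances of 0.0256, 0.0333 and 0.0433 against 0.0237, 0.0238 and 0.0239. The 10 came to 6, 5 and 6 without ethylene replicate 1, control replicate 3 and ethylene replicate 3, and AT3G10185 lost its call with ethylene without ethylene replicate 3 (0.121). The 46 came to 20 and 15 without control replicates 1 and 2 and to 24 and 28 without ethylene replicates 1 and 2. With ethylene, AT3G60070 lost its call without control replicate 1 (0.108) or 2 (0.247) or ethylene replicate 2 (0.0991) or 3 (0.0687), AT5G14580 without control replicate 1 (0.0670) or 2 (0.0544) or ethylene replicate 3 (0.0597), and AT4G13540 without any array but control replicate 3 (0.0548 to 0.182). With shade, AT3G60070 lost it without control replicate 2 (0.0732) or shade replicate 3 (0.0530), and AT4G13540 without control replicate 1 (0.168) or 2 (0.153) or shade replicate 1 (0.180) or 2 (0.0595). The 206 came to 122, 128 and 132 without control replicates 1 and 2 and ethylene replicate 2, and STZ lost its call with ethylene without control replicate 2 (0.0705) or 3 (0.0509) or ethylene replicate 3 (0.0781).

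Compared directly, shade and ethylene differed in hypocotyls in 2947, 2580 and 3502 genes at the 3 times and in cotyledons in 386, 841 and 2165. Shade was the higher in 720, 1437 and 1725 of these in hypocotyls, and in 213, 500 and 1110 in cotyledons. In hypocotyls at 25.5 h the glycosyltransferase UGT75C1 rose with ethylene (1.23 ± 0.45) and fell with shade (-2.53 ± 0.45), and GID1B did likewise (1.28 ± 0.27 and -1.44 ± 0.27). In cotyledons at 25.5 h 5MAT rose with ethylene (2.31 ± 0.43) and fell with shade (-1.48 ± 0.43). Quantile normalization gave 1298 higher and 969 lower with shade in hypocotyls at 1.5 h and turned the balance at 13.5 h, to 1232 higher and 1388 lower, and gave 273 and 139 and then 1543 and 755 in cotyledons at 1.5 and 25.5 h. Centring on reference genes gave 873 and 1119 and then 1763 and 775 in hypocotyls at 1.5 and 13.5 h, and 133 and 178 and then 534 and 198 in cotyledons at the same times. In cotyledons the 386 came to 240 without ethylene replicate 2 and 229 without shade replicate 2, and the 841 to 538, 549 and 548 without shade replicate 1, ethylene replicate 2 and shade replicate 2.

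Control hypocotyls and cotyledons were compared to see how far the tissues differ without treatment. At 1.5 h the extensin-like wall genes AT3G28550 (6.96 ± 1.06, adjusted p = 6.7e-07) and AT3G54580 (6.26 ± 1.00) and the subtilase SBT4.12 (6.23 ± 0.37) were higher in hypocotyl, and AT3G16660 (-7.10 ± 0.54, adjusted p = 4.2e-14), AT5G16030 (-5.95 ± 0.59) and AT1G33811 (-5.93 ± 0.33) lower. At 13.5 h AT3G54580 (6.65 ± 1.00), AT3G28550 (6.31 ± 1.06) and SBT4.12 (5.83 ± 0.37) were again higher and AT3G16660 (-8.34 ± 0.54), AT3G05730 (-5.24 ± 0.28) and AT2G32880 (-5.05 ± 0.32) lower. At 25.5 h AT3G54580 (6.06 ± 1.00), AT2G43150 (5.26 ± 0.59) and AT5G06800 (4.94 ± 0.36) were higher and AT3G16660 (-8.57 ± 0.54), AT1G66100 (-5.94 ± 0.49) and AT3G16670 (-5.67 ± 0.32) lower. AT3G54580 is also a root hair gene, and 10 root hair genes averaged 8.08, 7.93 and 6.11 in control hypocotyls at 1.5 h against 3.204, 2.94 and 2.88 in control cotyledons. The tissues differed in 7454, 5331 and 5342 genes, with 4723, 2732 and 2805 higher in hypocotyl and 2731, 2599 and 2537 lower. Centring on reference genes gave 3496 and 3556, 3211 and 1899, and 2208 and 3221, with the median of all genes at -0.16 at 25.5 h.

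Control arrays at 25.5 h were set against those at 1.5 h to see how much the seedlings changed without treatment. In hypocotyls AT1G22690 (4.65 ± 0.46, adjusted p = 2.1e-10), AT3G28270 (4.58 ± 0.39) and AT4G01390 (4.57 ± 0.45) rose, and AT2G47780, of the rubber elongation factor family (-6.10 ± 0.59, adjusted p = 1.3e-10), the peroxidase AT4G26010 (-5.98 ± 0.67) and AT3G23470 (-5.97 ± 0.97) fell. In cotyledons BGLU33 (4.65 ± 0.34, adjusted p = 2.9e-13), AT1G08160 (4.05 ± 0.39) and AT1G66100 (3.78 ± 0.49) rose, and AT5G44440 (-5.79 ± 0.52, adjusted p = 5.5e-11), AT2G47780 (-5.54 ± 0.59) and the lipid transfer protein AT4G22490 (-4.69 ± 0.53) fell. AT4G26010 is a root hair gene, and the means of 10 such genes went from 8.08, 7.93 and 6.11 in the control hypocotyls at 1.5 h to 3.37, 3.35 and 3.53 at 25.5 h. In hypocotyls 1764 genes were higher and 3821 lower, in cotyledons 1239 and 1738, and the hypocotyl count of 5585 came to 3123 without the arrays high in lectins. Quantile normalization gave 2319 and 3069, and 1622 and 1295, while centring gave 3081 and 2169, and, with the median of all genes at 0.18, 2240 and 1014.

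In hypocotyls most of the early ethylene rises lasted. Of the 242 hypocotyl genes higher at 1.5 h, 161 were higher at 13.5 h and 174 at 25.5 h, where independent lists would share 14.5 and 28.6, and AT1G44830 is among them. In cotyledons 39 of 93 higher genes were higher at 13.5 h and 59 at 25.5 h, against 0.882 and 2.64 for independent lists. Of the 288 hypocotyl genes lower at 1.5 h, 79 were lower and 71 higher at 25.5 h, XTH16 and XTH33 among the latter. In hypocotyls under shade 142 of the 343 genes higher at 1.5 h and 340 of the 1836 lower were called the same way again at 25.5 h, against 26.8 and 137 for independent lists, and 9 and 32 the opposite way. At 13.5 h it was 85 and 193 the same way, against 20.9 and 86.2, and 13 and 58 the opposite way. Between tissues, 221 genes were higher in both and 117 lower in both after 25.5 h of ethylene, where independent lists would share 58.7 and 45.8, and 345 and 264 after 25.5 h of shade, where they would share 67.2 and 51.1. Opposite ways went 94 genes higher and 48 lower in hypocotyl under ethylene, and 8 and 17 under shade. What independent lists would share was not worked out for these opposite counts. They draw on 497 higher and 413 lower genes in cotyledons under ethylene and 859 and 683 under shade. Across genes the changes of the tissues correlated at 0.241 with ethylene and 0.368 with shade at 25.5 h.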

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

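The tests on lectins, except that on root tissue, and the tests on normalization and on arrays high in lectins were chosen only after the result was seen. The response to ethylene differed between hypocotyl and cotyledon in 24, 547 and 2582 genes at 1.5, 13.5 and 25.5 h, and the response to shade in 378, 685 and 986. Features without a gene name that differed from control in at least 1 treatment contrast numbered 7750 of 20904, up to 3964 in hypocotyls after 25.5 h of ethylene, and what they measure is not analysed here.

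Jacalin-type lectin genes, which are expressed in roots, averaged 7.28 and 7.78 in control replicates 1 and 3 of the 1.5 h hypocotyls, and 7.57 and 6.48 at 13.5 h, a median of 5.53 and 5.67 above replicate 2. Root tissue left on some hypocotyls might explain this, but 19 mature root genes chosen beforehand differed between replicates 1 and 3 and replicate 2 by a median of -0.0891 at 1.5 h and 0.0844 at 13.5 h, under the bound of 0.5 written down as speaking against root tissue. That bound was judged unsuitable after the result, because 10 of these genes already lay above 5 in replicate 2 at 1.5 h, so the test is left open: 4 of 19 were higher by over 1 at each time, up to 3.43 and 4.29, and root hair genes went apart, at -0.750 and 1.44. Cotyledon tissue could not have brought the lectins in, since the highest cotyledon array reached 4.37. The median difference over the features that carry a gene was at most 0.0102. RMA equalizes the distributions, so this cannot exclude a general difference in signal. In all, 148 features that carry a gene were over 1 higher in the mean of replicates 1 and 3 than in replicate 2 at both times. Another 6 were over 1 lower.

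In hypocotyls after 1.5 h of shade, 1836 of 2179 called genes were lower. Unequal array distributions could explain this balance, because after quantile normalization within the tissue falls made up 46.7% of the calls, but a real loss of RNA from many genes would be evened out too. The shaded arrays had the lowest medians over all features of all arrays, at 4.15, 4.15 and 4.19. Their controls had medians of 4.51, 4.37 and 4.47. Dim features do not account for it, with 82.2% falls left once the dimmest were taken out. Falls made up 85.5% without the arrays high in lectins, but this leaves root tissue open, because the control array kept had root hair genes at a mean of 7.93, against 8.08 and 6.11 in those left out. The shaded arrays had them at 7.47, 8.24 and 6.91, no lower than the controls, but with a spread too wide to exclude root cells.

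Regrouping the arrays asks how often other splits of the same arrays give as many calls. For the 23 comparisons of 3 with 3 arrays the real split was the largest, 1 of 10, and these splits are too few for a share under 0.05. The highest other counts for ethylene in hypocotyls were 100, 159 and 7 against 530, 2109 and 4007, for shade 91, 177 and 44 against 2179, 1890 and 2678, for ethylene in cotyledons 3, 12 and 19 against 176, 282 and 910, and for shade 2, 15 and 25 against 92, 795 and 1542. Between shade and ethylene they were 9, 214 and 11 in hypocotyls against 2947, 2580 and 3502, and 1, 35 and 15 in cotyledons against 386, 841 and 2165. For the control tissues they were 4, 27 and 1 against 7454, 5331 and 5342, and for time 14 and 3 against 5585 and 2977.

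Of 100 splits of the tissue differences, with the shared treatment effect taken out, only the real one, 1 of 100, was as large, with highest other counts of 10, 23 and 827 for ethylene and 35, 269 and 382 for shade. This version was chosen after the result of an earlier one was seen, in which the shared effect stayed in and 14, 13 and 3 of 100 splits were as large for ethylene and 6, 6 and 7 for shade, with highest other counts of 631, 2015 and 2746 and of 861, 1989 and 3225. For the genes changed the same way, 6, 3 and 2 of 100 splits were as large in hypocotyls and 5, 5 and 4 in cotyledons, with highest other counts of 1497, 1117 and 1651 and of 121, 295 and 908. In several of these a split called many times the real count, which points to structure of the samples: a split that puts a treated group in the place of the controls shares that group's changes.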

How the results depend on the processing

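The counts per comparison, the counts changed the same way, the list calls and the genes named by size of change were refitted where an alternative applies. Genes named only as members of a list or family were not refitted singly, so their calls were not checked against these alternatives. The 25 list calls were not refitted over all features, without the arrays high in lectins or with the lectins as covariate. Of 200 named gene and contrast pairs, 57 lost their call under some alternative at the same threshold and 1 reversed, AT1G50060 in hypocotyls after 1.5 h of ethylene, at 0.25 without the arrays high in lectins; the cause was not tested. The calls lost numbered 48 with the compared arrays alone, 25 at an adjusted p below 0.01, 11 with the tissue alone (135 kept, contrasts between tissues not fitted), 7 over all features, 6 with a trended prior, 4 each with quantile normalization and with centring, 27 without the arrays high in lectins (72 kept, the others not refitted) and 23 with the lectins as covariate, and 143 in refits without an array, in which 1273 were kept. None of the 200 was lost with the replicate block, and none of the 181 that remain without features under 2.78 log2, which left 11590 features. Of the list calls 11 held with an estimated correlation, and 6 were lost without the dimmest features, 6 at an adjusted p below 0.01, 2 with the compared arrays alone, 1 with quantile normalization and 9 in refits without an array, in which 141 were kept. Counts in what follows run over 1.5, 13.5 and 25.5 h. With the compared arrays alone, where fewer arrays estimate the spread, ethylene changed 230 and 741 genes in hypocotyls (first 2 times) and 86, 87 and 485 in cotyledons, and shade 809, 300 and 1646, and 25, 91 and 470. Tissue differences came to 14 and 147 (ethylene, first 2 times) and 201, 66 and 525 (shade), shade against ethylene to 1646 (hypocotyl, 13.5 h) and 229, 189 and 1125 (cotyledon), and genes changed the same way to 17, 76 and 888, and 3, 2 and 60. At an adjusted p below 0.01, ethylene changed 296 and 1357 (hypocotyl, first 2 times) and 99, 157 and 469, and shade 981, 1092 and 1782, and 50, 311 and 786. Tissue differences came to 13 and 236 (ethylene, first 2 times) and 83, 236 and 486 (shade), shade against ethylene to 1676 and 1690 (hypocotyl, first 2 times) and 205, 406 and 1237, time in cotyledon controls to 1951, and genes changed the same way to 22, 306 and 942, and 6, 10 and 75. At 1.5 h, the tissue difference under shade was 171 with quantile normalization, 143 with centring, 233 over all features and 198 with the lectin covariate, and shade changed 1353 hypocotyl genes with centring and 1090 with the covariate. Genes changed the same way in hypocotyls at 1.5 h were 41 with the tissue alone and 41 with the covariate. Without the arrays high in lectins, which leaves 1 control array at 1.5 and at 13.5 h in hypocotyls, assumed to vary like the others, the 1.5 h counts were 199 (ethylene), 372 (shade), 13 and 88 (tissue differences) and 9 (the same way), and 3123 for time in hypocotyl controls. Leaving out each array gave, at 1.5 h, 342 to 641 (hypocotyl, ethylene), 1335 to 1969 (hypocotyl, shade), 111 to 140 (cotyledon, ethylene), 53 to 80 (cotyledon, shade), 17 to 88 and 200 to 493 (tissue difference, ethylene and shade), 24 to 273 and 5 to 13 (the same way, hypocotyl and cotyledon) and 229 to 335 (shade against ethylene, cotyledon). At 13.5 h it gave 1190 to 1830 (hypocotyl, shade), 141 to 318 (cotyledon, ethylene), 443 to 647 (cotyledon, shade), 305 to 668 and 329 to 869 (tissue difference), 15 to 67 (the same way, cotyledon) and 538 to 827 (shade against ethylene, cotyledon), and at 25.5 h 605 to 765, 1001 to 1301 and 122 to 188 (cotyledon, ethylene, shade and the same way). With the replicate number as block, 75 genes in place of 46 went the same way in cotyledons at 13.5 h, and no other count moved by over 1.5 times; residuals of arrays with the same number correlated at a mean of 0.0491 in hypocotyls and 0.0397 in cotyledons, and 18 of 27 and 24 of 27 arrays lay closest to their own number, a hint from the data and not from the design.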

Other observations

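The gene families here, and the tests on light at sampling, were chosen only after the result was seen. In hypocotyls at 25.5 h cellulose synthase-like genes, which make hemicelluloses, rose as a family of 9 genes under both treatments, with adjusted p-values of 0.0424 and 0.00954 over 336 tests (adjusted p = 0.107 and 0.0648 with an estimated correlation). Under ethylene 6 rose, among them CSLC04 (1.92 ± 0.17) and CSLC5 (1.18 ± 0.13), both of a group that makes the xyloglucan backbone, and CSLB03 fell (-3.54 ± 0.29, n = 3 arrays per group). Under shade 6 rose as well, among them CSLC04 (1.87 ± 0.17), CSLA03 (1.28 ± 0.14) and CSLC12 (1.11 ± 0.19), and CSLB03 fell (-2.68 ± 0.29). The adjusted p of the family under ethylene was 0.0545 after quantile normalization.

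UDP-glycosyltransferases, which attach sugars to small molecules, fell as a family at the same time. The 51 are those that the platform table names UGT, which leaves out UGT75C1 and UGT79B1 of the flavonoid list, and UGT75C1 rose with ethylene (1.23 ± 0.45). Of the 51, under ethylene 12 fell and none rose, among them UGT78D1 (-2.13 ± 0.19) and UGT73C6 (-1.48 ± 0.22), with an adjusted p of 0.0150 (adjusted p = 0.0976 with an estimated correlation). Under shade 10 of them fell and none rose, among them UGT72E1 (-2.14 ± 0.33) and UGT74B1 (-1.67 ± 0.20), with an adjusted p of 0.00954 (adjusted p = 0.0686 with an estimated correlation). Centring on reference genes gave 21 falls under ethylene and 12 under shade, and quantile normalization 12 and 9. Of 23 trichome birefringence-like genes, which acetylate wall polymers, 7 rose and none fell in hypocotyls after 13.5 h of shade, led by TBL19 (1.305 ± 0.28), TBL30 (1.26 ± 0.18) and TBL37 (1.06 ± 0.17), with an adjusted p of 0.0101 (adjusted p = 0.0976 with an estimated correlation). In cotyledons after 1.5 h of ethylene both wall families fell instead, the trichome birefringence-like genes with 2 called, TBL26 (-1.25 ± 0.22) and TBL45 (-0.53 ± 0.13), and an adjusted p of 0.0163 (adjusted p = 0.107 with an estimated correlation), and the cellulose synthase-like genes with none called and an adjusted p of 0.0424 (adjusted p = 0.107 with an estimated correlation, 0.0741 after quantile normalization). In all, 12 family tests were called and none with an estimated correlation. Photosynthesis genes encoded in the plastid were also called in hypocotyls. Relative to the other genes they were higher after 1.5 h of ethylene and of shade and lower after 13.5 h of shade. No member was called at 1.5 h, and the median of all genes under shade was then -0.116, so higher need not mean a rise. At 13.5 h psbM, ndhF, ndhI and ndhA fell. IQ-domain proteins were relatively higher in hypocotyls after 1.5 h of shade. Of these, IQD28 (0.51 ± 0.14), iqd21 (0.81 ± 0.25) and IQD26 (0.76 ± 0.19) rose and IQD16 fell (-1.30 ± 0.31). CLE peptides were relatively lower in cotyledons after 1.5 h of ethylene, with no member called. Quantile normalization ended the plastid calls (adjusted p = 0.0966, 0.989 and 0.323), with the second turned to lower, and that of IQ-domain proteins (0.0545).

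The 36 genes that rose in cotyledons after 1.5 h of shade, AT3G15450 and AKINBETA1 among them, were little changed in the dark at 13.5 h and up again at 25.5 h. Their median change was 0.922 at 1.5 h, 0.0983 at 13.5 h and 1.33 at 25.5 h, and 7 of them were called higher at 13.5 h and 31 at 25.5 h. A response that fades after transfer would not return to 1.33. A response that follows the light at sampling would give the low value of 0.0983, since control and shaded seedlings were both in darkness then. That explanation was chosen after the value was seen, so the value does not test it. The genes were picked by their rise at 1.5 h, which enlarges the value at that time, and the clock phase changes together with the light, so it could not be told apart from it.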
